A study of Mus musculus with 2 samples.

How the data were processed

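Single-cell libraries of sorted CD45-positive aortic cells were made with a 10x Chromium 3′ kit, per the labels' protocols, 1 library per marrow genotype. The values the authors deposited are raw counts, whole numbers of UMIs per gene and barcode in a filtered matrix, not normalised. The matrices were made with Cell Ranger 6.1.2, per the file headers, and the submitters' processing notes name Seurat 5.0.1, R 4.3.2 and the mm10 build. The gene annotation, the handling of intronic reads and the barcode calling settings are not given in the sources used here. Aortas of 7 mice are named in the labels, and whether that number is per group or in all is not stated. The 2 libraries were assigned to "WT marrow" and "Ehd1 KO marrow" from the labels. Gene positions are given for GRCm38/mm10 from the reference annotation, in which all 224 named genes and 32158 of the 32285 genes of the files were found by identifier.

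The WT library held 38267894 UMIs over 4717 barcodes (median 5166 UMIs and 1794 genes per barcode) and the KO library 36252607 UMIs over 5850 barcodes (median 3989 and 1498.5). Barcodes with fewer than 500 genes (119 WT and 79 KO) or over 10% mitochondrial UMIs (119 and 33) were left out, which left 4556 and 5762. Doublets were scored against 2 simulated doublets per barcode, and a share of 0.8% per 1000 barcodes was removed, 178 WT and 274 KO barcodes. The 4378 WT and 5488 KO cells kept held 34941612 and 32473381 UMIs. Intervals are exact at 95%, Poisson for levels, conditional binomial for ratios and Clopper-Pearson for shares, and cover counting error only. A count of 0 was bounded by a floor of 3 counts, which is 1.48 CPM in WT and 2.06 CPM in KO macrophage-like cells.

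Counts were scaled per cell and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 gave 24 clusters of both libraries together. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor and sex-linked genes and Ehd1 did not enter the clustering. The marker lists, gene lists, naming rule for genes and a first set of other settings were fixed before the data were examined. A marker's level in a cluster was scaled from 0 to 1 over the clusters on a log2 scale with a pseudocount of 10 CPM, and only types with 3 markers at a level of 0.5 seen in 25% of the cells could name a cluster. Of these types, X named it "X-like" where its mean level was the highest, was at least 0.5 and led the next such type by 0.05. Types short of 3 such markers did not compete, so cluster 3 is B cell-like beside a higher plasma cell level from 2 markers, and cluster 7 is T cell-like beside haemoglobin transcripts. A cluster in which 3 core genes of a second lineage were each seen in 50% of the cells was kept apart as mixed, which applied to cluster 8. The score and these thresholds were set after the data were seen. Cluster 17 met no name. Named classes with at least 100 cells in each library were compared, which were macrophage-, monocyte-, cDC2- and neutrophil-like cells. T cell- and B cell-like cells were compared within clusters of at least 100 cells per library, by number. Macrophage-like cells were clustered again with 1000 variable genes and 15 components.

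UMIs were summed per library and class and expressed as counts-per-million (CPM) values of the class total. With 1 library per group there is no test between groups, so no p-value is given. For each list the median log2 ratio of members with at least 20 UMIs was set against 10000 random lists of the same size drawn from 20 bins of mean expression, and its percentile is a description of these libraries. A member counted as higher or lower when the larger level exceeded the smaller by over 25%. The named genes were the 12 highest and 12 lowest ratios in macrophage-like cells and the 5 highest and 5 lowest in each other class, among genes with at least 100 UMIs, at least 20 CPM in the higher library, and a level there not below 0.5 times that of all other cells. Ehd1, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes and unnamed gene models were left out of this rule. From each list the 2 highest and 2 lowest members with at least 100 UMIs were eligible, and Ehd1 to Ehd4, Sort1, Il1b, Tnf, Ldlr and Apoe were always eligible. Ldlr, the gene disrupted in the recipient strain, gave 10 WT and 7 KO UMIs in macrophage-like cells. Core genes of a cell type are few markers from the fixed lists, such as Cd3e and Trac for T cells and C1qa and Csf1r for macrophages, chosen after the data were seen.

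The ratio step was tested on simulated counts for the macrophage-like comparison with 3959 genes, 200 of them changed. Both libraries were drawn as Poisson counts from a shared profile, without variation between cells or replicate libraries. Coverage near 95% thus checks the calculation and not the spread of real data. At simulated folds of 1.5, 2 and 4 the 95% intervals covered the true ratio for 95.7%, 95.2% and 95.9% of genes, 100.0% of the changed genes had the right sign, and the median error was 0.11, 0.10 and 0.13 on the log2 scale. A raised list of 15 genes lay at percentile 100.0, and an unchanged list at 88.2, 8.61 and 60.6.

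The first set of other settings was a minimum of 200 or 1000 genes, a limit of 5% or 20% mitochondrial UMIs, no doublet removal, resolution 0.5 or 2, components centred by library, classes set cell by cell, cells or clusters of a class weighted equally, TMM and median-of-ratios scaling, thinning to 1500 UMIs per cell, and list members with any UMI or at least 100. Added after the data were seen were leaving out barcodes with at least 4 core UMIs of 2 lineages, including the mixed cluster, leaving out the top cell of each gene, averaging each gene over the 4 of 7 macrophage sub-clusters with at least 20 cells per library, where either library held more than 3 UMIs of it, shares outside T cell-like and mixed clusters, and clustering without the 142 named genes. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2.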

Results

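Single-cell RNA sequencing was carried out on CD45-positive, DAPI-negative cells sorted from aortas of male Ldlr-deficient mice, a strain that develops atherosclerosis on a fat-rich diet. The mice had been irradiated and given bone marrow from wild-type (WT) donors or from donors lacking Ehd1 (KO), and ate a high-fat diet for 12 weeks up to an age of 26 weeks. Ehd1 encodes an ATPase that shapes membranes and returns cargo from endosomes to the cell surface. Aortas were pooled before sorting, and each marrow genotype gave 1 library. The WT library held 4717 barcodes with 38267894 UMIs and the KO library 5850 barcodes with 36252607 UMIs. After filtering, 4378 WT and 5488 KO cells remained, with a median of 5146 and 3810.5 UMIs per cell. Because each group is 1 library, no difference below has a replicate check and none was tested. Each value describes these libraries, and the 95% intervals (Poisson for levels, conditional binomial for ratios, Clopper-Pearson for shares) cover counting error only. Levels are counts-per-million (CPM) values within the UMIs of the stated group of cells, and log2 ratios are KO over WT.

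Ehd1, the targeted gene (ENSMUSG00000024772, chromosome 19, 6276725 to 6300096, GRCm38/mm10), was lower in the KO library. Over all kept cells it stood at 35.9 CPM (34.0 to 38.0) in the WT library and 7.98 CPM (7.03 to 9.01) in the KO library, a log2 ratio of -2.17 (-2.37 to -1.98). Macrophage-like cells held 122 WT and 8 KO Ehd1 UMIs, or 60.2 against 5.50 CPM, a log2 ratio of -3.45 (-4.70 to -2.43), which ranged from -3.78 to -2.22 over the other settings tried. Monocyte-like cells gave 47.0 and 5.41 CPM (log2 ratio -3.12), cDC2-like cells 55.5 and 7.47 (-2.89), and neutrophil-like cells 138 and 24.6 (-2.49). Over the other settings these ranged from -4.05 to -2.003, -2.96 to -1.39 and -2.93 to -2.20, with the smallest differences after thinning to 1500 UMIs per cell. All T cell-like cells gave 12.4 and 5.25 CPM (-1.24, -1.65 to -0.85). Within them cluster 10 gave 26.9 and 6.03 CPM (-2.16, -3.87 to -0.81), while in cluster 1, which expressed Rag1, the levels were 4.65 and 4.47 CPM (-0.06, -1.65 to 1.60). The deleted exons are not given in the sources used here. A 3′ tag outside the deleted part checks nothing, so the remaining KO counts do not show whether intact transcript was present. Of the relatives of Ehd1, Ehd4 was at 289.5 CPM in WT and 237 in KO macrophage-like cells (log2 ratio -0.29, -0.48 to -0.09), and Ehd2 and Ehd3 gave 1 to 4 UMIs per library.

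**Figure D1:**
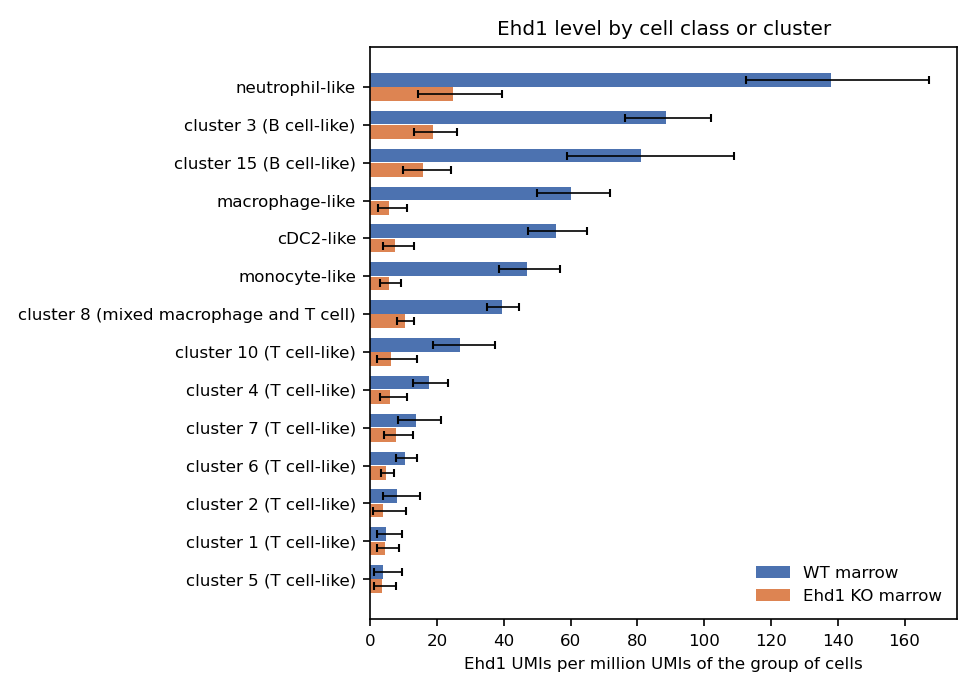
Ehd1 level in CPM within each group of cells (horizontal axis) in the WT marrow and Ehd1 KO marrow libraries, with bars for levels and whiskers for 95% Poisson intervals. The KO bar is the lower one in neutrophil-like (138 against 24.6) and macrophage-like cells (60.2 against 5.50), and both bars are low in T cell-like clusters 1 and 5.

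The next comparison asked how the make-up of the sorted aortic leukocytes differed between the marrow genotypes. Conventional type 2 dendritic cell-like (cDC2-like) cells, which present antigen to helper T cells, made up 4.50% (3.90 to 5.16) of kept WT cells and 2.57% (2.17 to 3.02) of kept KO cells. Type 1 dendritic cell-like (cDC1-like) cells made up 1.35% (1.03 to 1.73) and 0.692% (0.490 to 0.949), and natural killer (NK) cell-like cells 2.38% (1.94 to 2.87) and 1.42% (1.13 to 1.77). Outside T cell-like and mixed clusters the cDC2-like intervals stayed apart (10.7 to 14.0 and 6.74 to 9.32). There the intervals overlapped for cDC1-like (2.80 to 4.71 and 1.52 to 2.93) and NK cell-like cells (5.31 to 7.78 and 3.50 to 5.47). Macrophage-like cells were 242 of the WT cells, 5.53% (4.87 to 6.25), and 233 of the KO cells, 4.25% (3.73 to 4.81). This gap depended on the denominator and the class rule, with 15.05% (13.3 to 16.9) and 13.2% (11.6 to 14.8) outside T cell-like and mixed clusters, and 10.7% and 10.1% of kept cells when cells were classed one by one. Monocyte-like cells were the more frequent in the KO library, at 7.12% (6.46 to 7.84) against 5.76% (5.08 to 6.49). The monocyte gap came from cluster 11, led by Ace and Treml4 of patrolling monocytes, with 2.76% of WT and 4.35% of KO cells, while cluster 14, led by Chil3 and Vcan of classical monocytes, held 2.99% and 2.77%. Neutrophil-like cells made up 2.92% (2.44 to 3.47) and 3.21% (2.76 to 3.71), a difference within counting error, and 2.15% and 1.39% with a minimum of 1000 genes. Smaller classes were ILC2-like cells (0.662% and 0.383%), plasmacytoid dendritic cell-like (pDC-like) cells (0.434% and 0.346%) and migratory dendritic cell-like cells (0.594% and 0.200%). T cell-like clusters made up 57.6% and 60.6% of kept cells. T cell- and B cell-like clusters with at least 100 cells in each library were compared by number. Of the B cell-like clusters only cluster 3 met this, with 9.708% (8.85 to 10.6) and 7.198% (6.53 to 7.91). B cell-like cluster 15, with 70 WT cells, held 1.599% (1.25 to 2.02) and 3.808% (3.32 to 4.35). Shares of T cell-like clusters went both ways. Clusters 1 (12.97% and 19.06%), 5, 6, 7 and 24 were more frequent in the KO library, and clusters 2, 4 (9.89% and 6.23%), 10 and 19 less.

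Because several named genes help to define clusters, cells were also clustered without the 142 genes named by the rule. The shares were then 4.84% and 2.90% for cDC2-like, 5.48% and 4.23% for macrophage-like and 5.76% and 7.18% for monocyte-like cells. Cluster 8 carried macrophage and T cell transcripts in the same barcodes and was left out of both classes by a threshold set after the data were seen. It held 5.69% (5.02 to 6.42) of WT and 7.11% (6.44 to 7.82) of KO cells, more than the macrophage-like class itself in either library. Its T cell core genes (the Cd3 chains and T cell receptor constant genes) stood at 4369 CPM in the WT and 4958 CPM in the KO library, beside 9564 and 9955 CPM in T cell-like clusters. Over both libraries it also carried the immature T cell genes Rag1 (242 CPM), Dntt (187 CPM) and Arpp21 (173 CPM), with Rag1 at 12.4 CPM in the main macrophage-like cluster 9. A further cluster, 17, led by Lyz1, Retnla and Fn1, stayed unnamed and held 1.30% and 1.08%. Shares depend on the sort and on barcode calling, and the KO library was the shallower one.

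**Figure D2:**
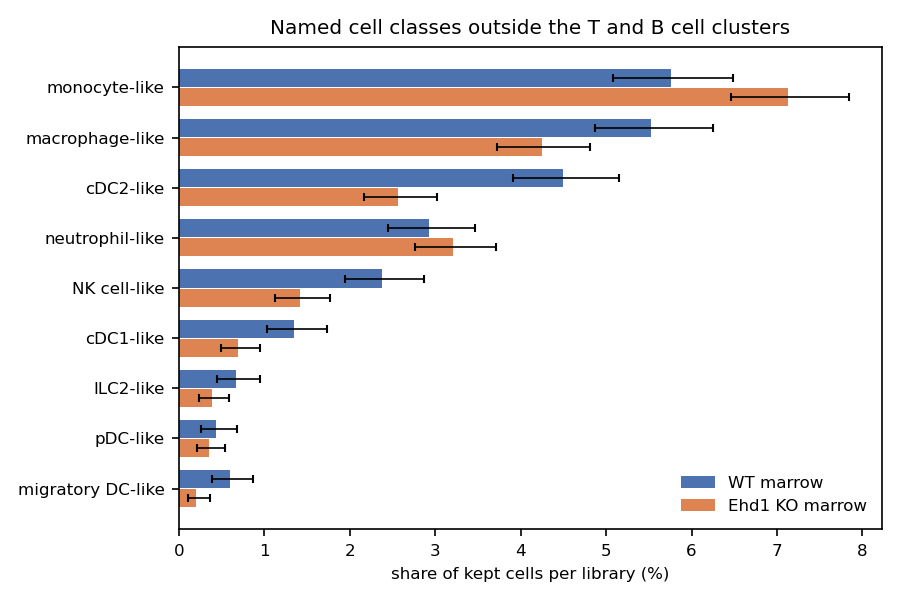
Share of kept cells per library (percent, horizontal axis) for the named classes outside the T and B cell clusters, with bars for the WT marrow and Ehd1 KO marrow libraries and whiskers for 95% Clopper-Pearson intervals. The cDC2-like bars (4.50% and 2.57%) do not overlap in their intervals, and the neutrophil-like bars (2.92% and 3.21%) do.

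**Figure D3:**
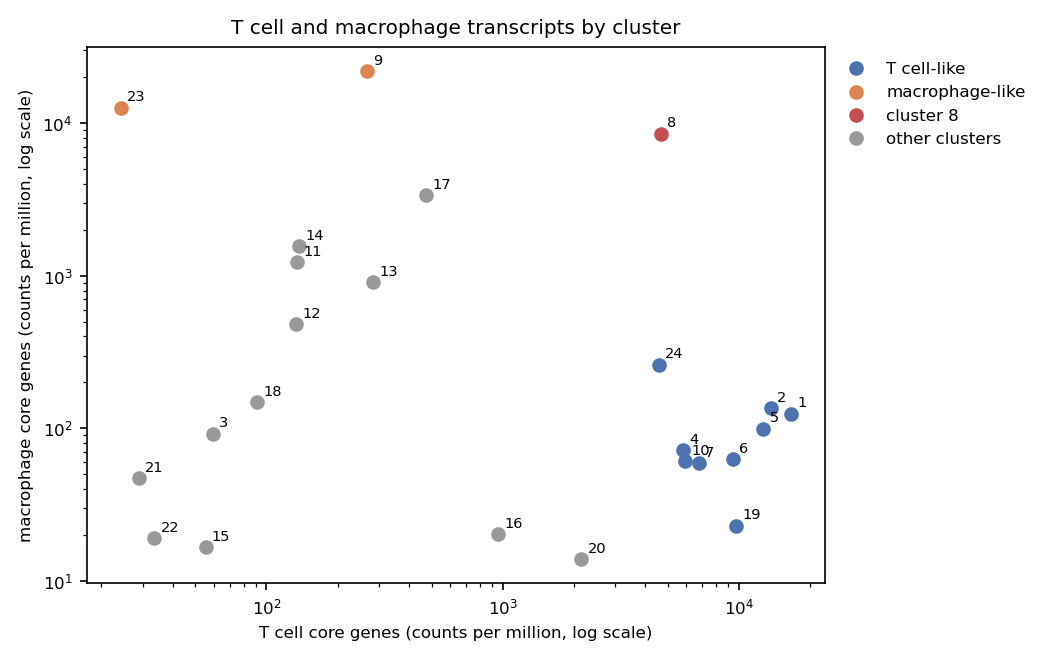
T cell core genes (horizontal axis) against macrophage core genes (vertical axis), both in CPM on log scales, with 1 point for each of 24 clusters over both libraries. Cluster 8 alone lies high on both axes, at 4668 CPM for T cell and 8540 CPM for macrophage core genes over both libraries.

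Macrophages are the cells that the series title names, and they formed the main comparison of expression, resting on 2027370 WT and 1453921 KO UMIs. Genes of resident tissue macrophages were higher in the KO library. All 11 measured members of the resident list were higher, with a median log2 ratio of 0.65 (0.50 to 0.77), above every one of 10000 random lists matched on expression (95% of these between -0.21 and 0.16), and of 0.15 when cells were classed one by one and 0.13 with cluster 8 included. Lyve1, a hyaluronan receptor (chromosome 7, 110850607 to 110863239), stood at 43.4 CPM in WT and 154 CPM in KO cells (log2 ratio 1.83, 1.47 to 2.20). Cd163, the haemoglobin scavenger receptor (chromosome 6, 124304656 to 124330527), stood at 43.4 and 140.3 CPM (1.69, 1.33 to 2.07). The list of receptors for modified LDL, which shares Mrc1 and Stab1 with the resident list, had a median of 0.41 (0.27 to 0.57), with 6 of 8 members over 25% higher. Within the 4 sub-clusters with at least 20 cells in each library its medians were 0.15, 0.17, -0.14 and -0.18, each with a counting range across 0, and with each gene averaged over them it was -0.068. Cd36, a scavenger receptor for oxidised LDL, stood at 61.7 and 103 CPM (0.74, 0.39 to 1.10), and Lrp1 at 126 and 175 CPM (0.48).

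Sub-clustering of the macrophage-like cells gave a resident-like group, led by Lyve1, Folr2 and Cd163, with 9.09% (5.79 to 13.4) of the WT and 19.7% (14.8 to 25.4) of the KO macrophages. With the named genes left out of clustering these shares were 11.7% and 22.0%, and with up to 20% mitochondrial UMIs 19.5% and 28.6%. Within sub-clusters the resident list went both ways, with a median log2 ratio of 0.03 (-0.10 to 0.17) in the resident-like group and of 0.38 (0.13 to 0.68), 0.26 (-0.03 to 0.44) and -0.41 (-0.76 to 0.03) in the other 3 sub-clusters with at least 20 cells in each library. With each gene first averaged over these 4 of 7 sub-clusters, the median was -0.06. A foamy-like group, led by Fabp5, Cd5l and Gpnmb, held 19 WT cells, 7.85% (4.79 to 12.0), and 11 KO cells, 4.72% (2.38 to 8.29), and 9.13% and 9.49% of macrophages with a minimum of 200 genes per cell. T cell core genes in the macrophage-like class were at 179 CPM (161 to 198) in WT and 376 CPM (345 to 408) in KO cells, and cDC2 markers at 399 and 726 CPM.

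Inflammatory genes were lower as a group in KO macrophage-like cells. The 21 measured cytokines and NF-kB targets had a median log2 ratio of -0.25 (-0.34 to -0.14), below all but 0.12% of random lists, with 9 over 25% lower and 2 over 25% higher. The size was uneven over the sub-clusters with at least 20 cells in each library. Their medians were -0.16 (-0.33 to -0.03), -0.12 (-0.19 to 0.18), -0.08 (-0.37 to 0.32) and -0.82 (-1.26 to -0.45), the last from 31 WT and 25 KO cells. Cxcl1, a neutrophil chemoattractant, stood at 124 CPM in WT and 53.0 CPM in KO cells (-1.23), although 26.7% of its WT and 46.8% of its KO UMIs lay in 1 cell. Tnfaip3, a brake on NF-kB signalling, stood at 148 and 94.9 CPM (-0.65, -0.95 to -0.35). Against the group, Il18 was at 36.0 and 51.6 CPM (0.52) and the monocyte chemoattractant Ccl7 at 547 and 740.1 CPM (0.44). Il1b was at 1169 and 1014 CPM (-0.20, -0.30 to -0.11, and -1.40 as a mean of the 4 larger sub-clusters), and Tnf at 265 and 257 CPM (-0.04, -0.24 to 0.15).

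Receptors for recruitment and adhesion were lower as well, with a median of -0.33 (-0.45 to -0.14) and 6 of 11 over 25% lower. In the 4 larger sub-clusters the medians were -0.46, -0.10 (-0.39 to 0.26), -0.34 and -0.89. Cx3cr1, the fractalkine receptor (chromosome 9, 119901616 to 120069879), stood at 658 and 343 CPM (-0.94, -1.09 to -0.79), and Ccr5 at 194 and 139.6 CPM (-0.48). Lysosomal genes had a median of -0.21 (-0.25 to -0.10, percentile 0.61), with Hexb at 705 and 537 CPM (-0.39) and Ctsl at 318 and 256 CPM (-0.31), while Hexa (0.22) and Lamp1 (0.20) were higher. Lipid-associated (foamy) genes had a median of -0.38 (-0.47 to -0.13, percentile 0.02), with 7 of 12 over 25% lower. In the foamy-like group itself the median was -0.83 (-1.52 to -0.56), while in the 4 larger sub-clusters it was -0.12, 0.04, 0.19 and 0.54 (0.31 to 0.96), and averaging each gene over these 4 gave 0.0097. Proliferation genes had a median of -1.34, which rested on 7 cycling cells, 6 of them WT, and was 0.14 with cluster 8 included. All 8 mitochondrially encoded transcripts were lower, with a median of -0.57 (-0.60 to -0.52), and mt-Co3 stood at 3503 and 2067 CPM. The median mitochondrial share per macrophage-like cell was 2.38% in WT and 1.68% in KO, and the median of this list was below 0 in each class and cluster compared. In neutrophil-like cells the list stood at -0.19, although the median share per cell was the higher in the KO library there (0.280% and 0.381%).

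**Figure D4:**
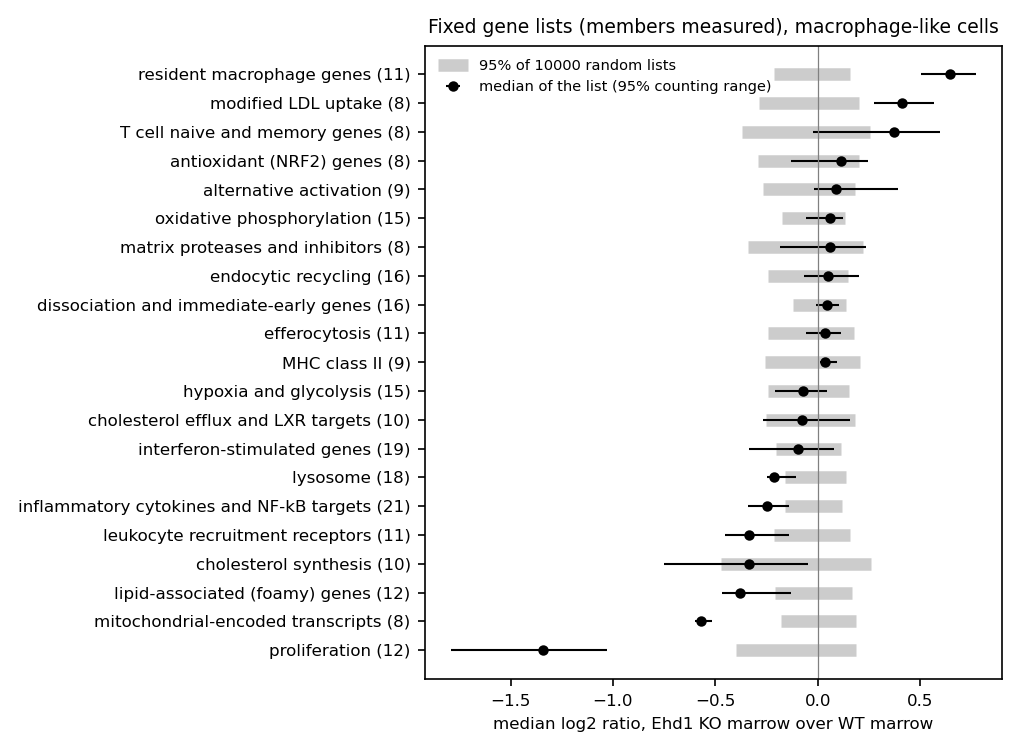
Median log2 ratio, Ehd1 KO marrow over WT marrow (horizontal axis), of the fixed gene lists in macrophage-like cells, with the number of measured members in brackets. Points are list medians with 95% counting ranges and grey bars hold 95% of 10000 random lists; resident genes (0.65) lie right of their grey bar and inflammatory genes (-0.25) left of it.

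Most other lists lay inside the range of random lists in macrophage-like cells. Interferon-stimulated genes had a median of -0.09 with 6 higher and 7 lower, since Irf7 (278 and 155 CPM, -0.84) and Oas1a (44.9 and 24.8 CPM, -0.86) opposed Rsad2 (2.38) and Cxcl10 (1.06), which were high in single KO cells. Cholesterol efflux and LXR targets had a median of -0.08, with Apoe (chromosome 7, 19696109 to 19699188), the main apolipoprotein of macrophages, at 13740 and 20621 CPM (0.59, 0.56 to 0.61) and Pltp at 454 and 679 CPM (0.58). The Apoe ratio was 0.27 when cells were classed one by one, 0.17 as a mean of the 4 larger sub-clusters and 0.15 with cluster 8 included. The cholesterol exporters Abcg1 (124 and 92.2 CPM, -0.43) and Abca1 (178 and 140.3 CPM, -0.34) went the other way. Cholesterol synthesis had a median of -0.34 (percentile 10.2), MHC class II 0.04, efferocytosis 0.04, matrix proteases 0.06, alternative activation 0.09, hypoxia and glycolysis -0.07, and oxidative phosphorylation 0.06. Antioxidant genes had a median of 0.11, with the haem-degrading enzyme Hmox1 at 205 and 400.3 CPM (0.96, 0.78 to 1.15). Dissociation and immediate-early genes, a sign of handling stress, had a median of 0.04, with Dnajb1 higher (0.73) and Nr4a1 lower (-0.95). The 16 endocytic recycling genes, which work beside EHD1, had a median of 0.05 (-0.07 to 0.20), with Rab11a, a GTPase of recycling endosomes, at 72.5 and 96.3 CPM (0.41). Lists of T cell genes in these cells had medians of 0.38 (naive and memory, percentile 99.6), -0.70 (effector, 4 members, percentile 0.62) and 0.39 (regulatory, 3 members), beside the higher T cell core level in the KO library, and of -0.18, 0.018 and -0.46 without barcodes of 2 lineages.

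The series title also names sortilin, the sorting receptor encoded by Sort1 (chromosome 3, 108284082 to 108361511). Macrophage-like cells held only 4 WT and 1 KO Sort1 UMIs, so a difference was not detectable at this depth (log2 ratio -1.52, -7.14 to 1.82). Monocyte-like cells held 84 and 76 UMIs, or 36.9 and 31.6 CPM (-0.22, -0.69 to 0.24), and neutrophil-like cells 27 and 15 UMIs (-0.75, -1.76 to 0.21). Its relative Sorl1, the remaining measured member of the sortilin family, stood at 22.7 and 30.3 CPM in macrophage-like cells (0.42, -0.21 to 1.04). These are transcript levels, and sortilin protein was not measured in the data used here.

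The size rule named 12 genes higher and 12 lower in KO macrophage-like cells. Fkbp5, a co-chaperone of steroid receptors (chromosome 17, 28399094 to 28517527), stood at 20.2 CPM in WT and 125 CPM in KO cells (log2 ratio 2.63, 2.13 to 3.16), from 30 and 104 cells. Tsc22d3, the glucocorticoid-induced leucine zipper (chromosome X, 140539528 to 140600659), stood at 156 and 481 CPM (1.62, 1.43 to 1.82), and the metallothionein Mt2 at 28.6 and 93.5 CPM (1.71). Sult1a1, a phenol sulfotransferase, stood at 21.2 and 97.0 CPM (2.19, 1.69 to 2.72), Apoc2 at 15.8 and 63.3 (2.003), Clec10a, also a cDC2 marker, at 36.5 and 111 (1.60) and Selenbp1 at 18.3 and 52.3 (1.52), beside Lyve1 and Cd163 above. Classing cells one by one and including cluster 8 gave smaller ratios, at 1.65 and 1.41 for Fkbp5, 1.04 and 1.16 for Lyve1, 0.92 and 0.97 for Cd163, 1.66 and 1.53 for Sult1a1, 0.96 and 0.80 for Tsc22d3, 0.65 and 1.01 for Mt2, 0.70 and 0.56 for Apoc2, 0.12 and 0.30 for Clec10a, and 0.72 and 0.63 for Selenbp1. Lyz1 (13.3 and 198 CPM, 3.89), Retnla (239 and 931 CPM, 1.96) and Rsad2 (43.9 and 228 CPM, 2.38) drew 26.7%, 52.0% and 47.9% of their KO UMIs from 1 cell each, and Lyz1 can share reads with Lyz2. The Lyz1 ratio was 1.20 with the named genes left out of clustering, 0.32 when cells were classed one by one and 0.41 with cluster 8 included, the Rsad2 ratio was 1.24 and 0.95 in the latter settings, and Retnla was lower in the KO library (-0.62) with cluster 8 included.

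Of the genes lower in KO macrophage-like cells, Cyp4f18, a hydroxylase of leukotriene B4 (chromosome 8, 71988482 to 72009626), stood at 63.6 and 6.19 CPM (-3.36, -4.52 to -2.39), from 79 WT and 4 KO cells. Tmem173, which encodes the DNA sensor adaptor STING, stood at 50.3 and 19.3 CPM (-1.39, -2.04 to -0.77), and Ch25h, which makes the oxysterol 25-hydroxycholesterol, at 110.5 and 50.2 CPM (-1.14, -1.54 to -0.75). Mpp7 stood at 47.4 and 17.2 CPM (-1.46) and Isg20 at 38.5 and 17.2 (-1.16), with 29.5% of its WT UMIs in 1 cell. Classing cells one by one and including cluster 8 gave -1.44 and -1.69 for Cyp4f18, -0.52 and -0.37 for Mpp7, and -0.22 and -0.37 for Isg20. Ftl1-ps1 (-1.40) and Rbmxl1 (-1.40) are near copies of Ftl1 and Rbmx, so their levels are uncertain. Fn1 (100.1 and 19.3 CPM), Areg (100.1 and 24.8 CPM) and Yae1d1 (149 and 60.5 CPM) had over 40% of their UMIs in 1 cell of each library. Prg4 had 163 WT and 0 KO UMIs, at least 39.0-fold lower against a floor of 3 counts, but 98.2% of the WT UMIs lay in 1 of 2 cells, so no ratio outside that cell is given.

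**Figure D5:**
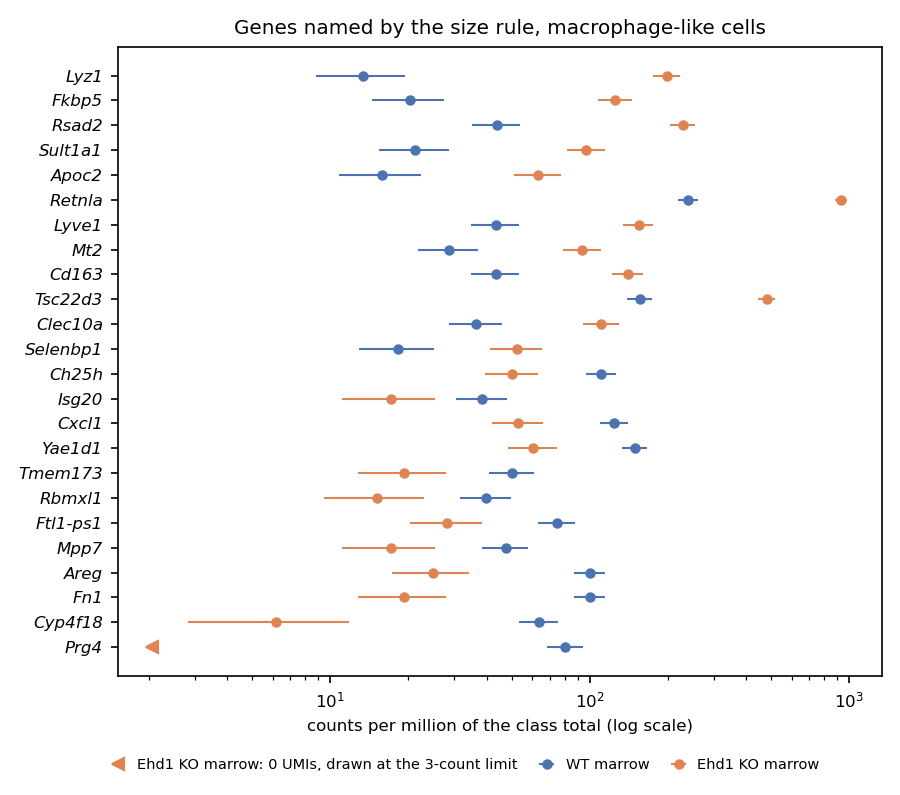
Level of each gene named by the size rule in macrophage-like cells, in CPM on a log axis, with points for the WT marrow and Ehd1 KO marrow libraries and lines for 95% Poisson intervals. Fkbp5 (20.2 and 125 CPM) and Cyp4f18 (63.6 and 6.19 CPM) lie far apart, and Prg4, with 0 KO UMIs, is drawn at its 3-count limit.

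Donor-derived cells of every class share the marrow genotype, so the other classes were compared in the same way. The share of cells in each class that stem from the recipients is not given in the sources used here. Monocyte-like cells of the KO library had lower MHC class II genes, with a median of -0.67 (-0.75 to -0.58), 8 of 9 over 25% lower and no random list below it. H2-Aa, an antigen-presenting chain (chromosome 17, 34282744 to 34287823), stood at 1887 and 1021 CPM (-0.89), and Ciita, the transactivator of the class II genes, at 35.6 and 12.5 CPM (-1.51, -2.17 to -0.89). The list was lower in both monocyte clusters, by -0.78 in cluster 11 and -0.46 in cluster 14. Recruitment receptors (-0.27, percentile 0.13), among them Ccr2 at 671 and 469 CPM (-0.52), and lysosomal genes (-0.21, percentile 0.15) were lower too. Gsr, glutathione reductase (chromosome 8, 33652523 to 33698163), stood at 533 and 91.1 CPM (-2.55, -2.76 to -2.34), from 225 and 152 cells. Slamf7 (54.5 and 22.5 CPM, -1.28) and Fgl2 (87.9 and 37.0 CPM, -1.25) were lower, and Fkbp5 (17.6 and 48.3 CPM, 1.46) and the kinase gene Ikbke (12.3 and 32.9 CPM, 1.42) were higher, and thinning to 1500 UMIs gave -0.49 for Fgl2, 2.70 for Fkbp5 and 0.75 for Ikbke. The inflammatory list lay within the random range (-0.11, percentile 8.04), with Ccl3 (68.5 and 134 CPM, 0.97) and Cxcl2 (463 and 832 CPM, 0.85) higher and Ccl5 (168 and 71.97 CPM, -1.22) lower. Cxcl10 (23.3 and 111 CPM) and Spp1 (45.7 and 19.1 CPM) rested largely on single cells, and T cell core genes were at 220.1 CPM in WT and 56.6 CPM in KO monocyte-like cells.

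In cDC2-like cells the inflammatory list was lower (-0.24, -0.33 to -0.14, percentile 0.88), with 7 of 20 members over 25% lower, among them the inflammasome gene Nlrp3 at 209.8 and 108 CPM (-0.95). Interferon-stimulated genes had a median of -0.32 (percentile 0.93), with Irf7 at 129 and 75.4 CPM (-0.78). Against the list, Cxcl10 stood at 17.6 and 72.2 CPM (2.04, 1.55 to 2.55), with 34.5% of its KO UMIs in 1 cell. Over the other settings its ratio ranged from 0.21 to 2.36. Isg20 (51.7 and 18.7 CPM, -1.47), Vegfa (47.1 and 18.7 CPM, -1.33) and the volume-regulated channel gene Lrrc8d (31.3 and 11.8 CPM, -1.40) were lower. Fkbp5 (10.2 and 45.5 CPM, 2.16, 1.52 to 2.83), Fxyd7 (11.2 and 44.2 CPM, 1.98) and Upb1 (14.1 and 39.2 CPM, 1.48) were higher. Cxcl9 (52.4 and 231 CPM) had over 55% of its UMIs in 1 cell of each library and a ratio of -0.48 with a minimum of 200 genes. Resident macrophage genes were higher (0.83, 6 members), and so were macrophage core genes (364 and 686 CPM) and T cell core genes (67.8 and 251 CPM) in the same cells. Thinning cells to 1500 UMIs gave ratios of 0.48 for Vegfa, 0.48 for Upb1, -0.52 for Lrrc8d and -3.32 for Isg20.

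Of the genes named as lower in KO neutrophil-like cells, Gsr had the widest gap, at 964 CPM in WT and 63.7 CPM in KO cells (-3.92, -4.39 to -3.48), from 118 and 36 cells. The chemokines Ccl4 (718 and 3025 CPM, 2.08, 1.94 to 2.22) and Ccl3 (365 and 1512 CPM, 2.05, 1.86 to 2.25), neighbours on chromosome 11, were higher in the KO library, with ratios of 0.74 and 0.24 when cells were classed one by one, and Il1b stood at 6699 and 9049 CPM (0.43). Alox5, the lipoxygenase that starts leukotriene synthesis, stood at 114 and 46.3 CPM (-1.29, -1.93 to -0.69). Ccl2 (347 and 33.3 CPM, -3.38), Selenop (151 and 31.9 CPM, -2.25) and Mafb (251 and 57.9 CPM, -2.12) were lower, and so were the macrophage core genes, at 1406 and 381 CPM. Retnla, Gzmb and Cxcl10 were higher in KO cells but rested on 5 or 6 cells each. The Ccl2 ratio was -1.19 when cells were classed one by one and -1.04 without doublet removal. When cells were classed one by one, Selenop (0.76) and Mafb (0.53) were higher and Retnla (-2.24) and Gzmb (-2.57) lower in the KO library.

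Among T cell-like clusters, cluster 4, led by Ccl5, Ifng and Gzmk of cytotoxic cells, held more Gzma, encoding granzyme A (chromosome 13, 113093825 to 113100981), in the KO library. Gzma stood at 148 and 1131 CPM there (2.93, 2.78 to 3.09), in 49 and 73 cells, and Gzmm, another granzyme, at 38.9 and 100.1 CPM (1.36). The NK receptor gene Klra9 went with them (13.8 and 59.9 CPM, 2.12, from 9 and 19 cells), and Gzma also leads NK cell-like cluster 16. In the same cluster interferon-stimulated genes had a median of -0.41 (percentile 0.03), with 11 of 16 over 25% lower, including Oas3 (29.8 and 12.6 CPM, -1.24, and -0.65 after thinning). Naive and memory genes were higher there (0.33, 0.10 to 0.40), with the interleukin-7 receptor gene Il7r at 373 and 651 CPM. Cluster 10, led by Il17a and Icos, had lower effector (-0.46, percentile 0.33) and inflammatory genes (-0.39, percentile 0.28). Against the effector list, its member Il17a was higher in the KO library (1.14, and 0.93 to 1.60 over the other settings). Irs2 (77.9 and 26.5 CPM, -1.55) and Fgl2 (157 and 56.7 CPM, -1.47) were lower in cluster 10. Slamf6 (38.2 and 91.6 CPM, 1.26) and Sh2d1a (65.9 and 148 CPM, 1.17) were higher. Cluster 3 was named B cell-like by its 7 markers, although its 10 leading genes, mostly immunoglobulin transcripts, held 2 plasma cell markers and 0 B cell markers. There Pik3ca (47.3 and 17.2 CPM, -1.46) and Mylip (69.8 and 25.6 CPM, -1.45) were lower in the KO library. Of its genes named as higher, the stromal transcripts Sfrp2, Col3a1, Fbln1 and Igfbp4 had UMIs in 3 to 8 KO cells, and Slpi in 24 KO and 11 WT cells, with 92.6% of the WT UMIs in 1 cell.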

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

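The tests of the first pair of patterns below and the subset test of the third were chosen after the result was seen, while the tests of glucocorticoid exposure and of loss of Ehd1 were written before their values.

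T cell core transcripts in cluster 8 drew attention because they lie outside the classes compared and above the level in dendritic cell-like barcodes of the same libraries, at 4369 CPM in the WT and 4958 CPM in the KO library, 45.7% and 49.8% of the level in T cell-like clusters. Free RNA from broken T cells at the level of conventional dendritic cell-like clusters (73.7 and 214 CPM) falls short, since cluster 8 was at least 23.2 times as high. Cluster 8 was set apart by detection of T cell core genes, however, so this gap was partly fixed by the rule. The comparison is therefore no independent exclusion of free RNA. Chance capture of 2 cells in a droplet stays open. Barcodes were taken before doublet removal where macrophage core UMIs reached 0.25 times their class median. Of 542 such WT and 705 such KO barcodes, 54.4% and 65.7% also held T cell core UMIs at that level. So did 27.1% and 28.8% of barcodes with B cell core UMIs and 18.1% and 21.7% of those with neutrophil core UMIs. The lowest ratio of shares was 2.01, and 1.65 between interval ends, short of the 3 times set on those ends for exclusion. Cluster 8 barcodes of the WT library held a median of 9 B cell core UMIs, with 6 needed to count. They can thus fill the B cell share, so this ratio cannot decide on chance capture. Whole T cells bound to or taken up by macrophages may account for the pattern as well. Mixed barcodes held a median of 93 and 69 T cell core UMIs against 41 and 31 per T cell-like barcode, at least 2.23 times as many. Mixed barcodes were also deeper, with a median of 23338 and 15260.5 UMIs in all against 3949 and 2678 per T cell-like barcode. The raw counts thus do not tell bound or engulfed T cells from 2 or more cells in a droplet. Over both libraries cluster 8 also held the immature T cell genes Rag1 (242 CPM), Dntt (187 CPM) and Arpp21 (173 CPM), as the Rag1 clusters below do, B cell core genes reached 12.6% and 12.0% of their own class's level and neutrophil core genes 0.823% and 0.9996%, and no explanation by marrow genotype was tested.

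T cell-like clusters 1, 2, 6 and 19 expressed Rag1, the recombinase gene of immature lymphocytes, at 583 CPM in the WT and 545 CPM in the KO library, and held 31.0% (29.6 to 32.4) and 34.7% (33.5 to 36.0) of kept cells. Free RNA is excluded, since Dntt and Arpp21, which did not enter the choice of these clusters by Rag1, together reached 1393 and 1299 CPM, at least 204 times the level in B cell-like clusters (6.83 and 3.09 CPM). Mature T cells alone fall short too, since 4 T cell-like clusters held both genes above 100 CPM. These are the same clusters that Rag1 chose, and Rag1, Dntt and Arpp21 could all enter the clustering. The count is therefore not independent of that choice. Thymus tissue taken along with the aorta may be a source, a hypothesis that the CD45 sort would not exclude and that the labels, which name the aorta, do not address. At 1500 UMIs per cell, Cd4 and Cd8b1 were both seen in 28.8% (26.3 to 31.4) of WT and 28.9% (26.7 to 31.2) of KO cells of these clusters, against 0.947% and 1.37% in other T cell-like clusters (at least 21.2 times) and 0 of 492 and 0 of 599 B cell-like cells, which allows up to 0.747% and 0.614%. Unthinned shares, in the same order, were 53.2% and 44.6%, 3.35% and 3.31%, and 0.202% and 0.166%. Median depths were 2725 and 1966, 5288 and 3775, and 4543 and 4710 UMIs. Cells too shallow to thin were 68 and 336, 4 and 29, and 3 and 5. No explanation by marrow genotype was tested.

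Genes known to respond to glucocorticoids (Fkbp5, Tsc22d3, Klf9, Mt1, Mt2 and Sgk1) were noticed as higher in the KO library. They were listed after they were noticed, so their medians describe the pattern and are no independent support for it. The median log2 ratios were 1.48 in macrophage-like, 1.08 in neutrophil-like, 0.96 in cDC2-like, 0.72 in B cell-like, 0.21 in monocyte-like and 0.089 in T cell-like cells. For these noticed genes a different mix of the 4 larger macrophage sub-clusters did not account for the whole gap in macrophage-like cells of these libraries. The range below covers counting error only, and finer subsets and the smaller sub-clusters stay open. Averaging each gene over the 4 larger sub-clusters left a median of 1.21 (0.83 to 1.60), at its lower limit over 0.5 times the median in the class. The same step took the resident list from 0.65 to -0.059. Exposure of the KO library's cells to glucocorticoids cannot be decided, because a second list, written before its values were seen, lay above the 95% range of random lists in 2 of 6 classes, macrophage-like (0.53) and cDC2-like cells (0.40), with 0.19 in monocyte-like, 0.10 in T cell-like, 0.07 in neutrophil-like and -0.04 in B cell-like cells. Loss of Ehd1 in the marrow could not be separated from other differences between the libraries, since each genotype is 1 library. Hormone levels, housing and time of collection are not given in the sources used here.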

How the results depend on the processing

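No paired analysis was possible because each genotype is 1 library. Alternatives chosen after seeing the data were leaving out barcodes with 2 lineages, including the mixed cluster, leaving out each gene's top cell, averaging sub-clusters, shares outside T cell-like and mixed clusters, and clustering without the named genes. Over all results and alternatives 1926 values were counted as the same, 305 as moved beyond their counting interval and 31 as reversed. Some values counted as moved also changed sign. With the mixed cluster included, cholesterol synthesis in macrophage-like cells went from -0.34 to 0.089 and alternative activation from 0.09 to -0.27. No ratio is given where a gene had at most 3 UMIs in both libraries, as Prg4 did in macrophage-like cells under 7 alternatives and in monocyte-like cells under 2, Mafb in neutrophil-like cells without barcodes of 2 lineages, and Col3a1 in cluster 3 without its top cell. The direction held under each alternative run for Ehd1 (-3.78 to -2.22), the inflammatory (-0.41 to -0.13), lysosome (-0.31 to -0.12), recruitment (-0.47 to -0.09) and mitochondrial lists (-0.61 to -0.49) in macrophage-like cells. It also held for Fkbp5 (1.41 to 2.997), Lyve1 (0.90 to 2.06) and Cyp4f18 (-4.83 to -1.44) there, and for Gsr in monocyte-like (-2.67 to -2.47) and neutrophil-like cells (-4.64 to -3.48). Shares of cDC2-like cells were 4.41% to 5.53% in WT and 2.46% to 3.12% in KO, and of monocyte-like cells 4.71% to 6.00% and 6.05% to 8.12%. The median ratios of the resident and modified LDL lists were above 0 in 20 of 21 alternatives and that of the foamy list below 0 in 19 of 21. No result was counted as reversed under TMM and median-of-ratios scaling, resolution 0.5 and 2, components centred by library, the mean of clusters, leaving out top cells and clustering without the named genes. The B cell-like class as a whole shifted by -0.11 under median-of-ratios scaling. Clusters compared by number have no matched value where cells were clustered anew. Depth limits genes with few UMIs, as thinning left 230 WT and 217 KO macrophage-like cells, with 12 and 16 too shallow.

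In the values that follow, log2 ratios are for macrophage-like cells where no class is named, and the cause was not tested except where the setting itself removes the cells or genes named. With a minimum of 200 genes the KO macrophage-like share was 4.95%, the inflammatory list -0.41, the resident list 0.43, Prg4 in monocyte-like cells -0.018 and Cxcl9 in cDC2-like cells -0.48. A minimum of 1000 genes gave Prg4 -0.33 in monocyte-like cells. A limit of 5% mitochondrial UMIs gave Prg4 -0.012 in monocyte-like and Cxcl9 -1.37 in cDC2-like cells. At 20% the resident-like shares were 19.5% and 28.6%, Prg4 in monocyte-like cells -0.12 and Cxcl9 in cDC2-like cells -0.13. Without doublet removal Prg4 was -0.040 in monocyte-like cells and the T cell naive and memory list -0.057. Cell-by-cell classes gave macrophage-like shares of 10.7% and 10.1%, Retnla -0.14, the foamy list 0.042, the resident list 0.15, and in neutrophil-like cells Retnla -2.24, Gzmb -2.57, Selenop 0.76 and Mafb 0.53. Leaving out barcodes with 2 lineages gave resident-like shares of 15.1% and 27.1%, Prg4 -0.46 in monocyte-like cells, the inflammatory list -0.13, the resident list 0.82, T cell effector genes 0.018, naive and memory genes -0.18, and Retnla -0.70 in neutrophil-like cells. Weighting cells equally gave -0.13 for the inflammatory list. Thinning to 1500 UMIs gave Ehd1 -2.31, naive and memory genes -0.12, Vegfa in cDC2-like cells 0.48, and in cluster 6 Ehd1 0.10 and Id1 -0.14. List members with any UMI gave 0.10 for the EHD family and 0.065 for T cell effector genes, and members with at least 100 UMIs -0.32 for naive and memory genes. With the mixed cluster included Ehd1 was -2.22, Retnla -0.62, the resident list 0.13 and proliferation 0.14. The mean of the 4 larger sub-clusters, which by construction leaves out the foamy-like and cycling groups, gave -0.068 for the modified LDL list, 0.0097 for the foamy list and -0.059 for the resident list. Of cells outside T cell-like and mixed clusters, macrophage-like cells made up 15.05% and 13.2%.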

Other observations

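The test of the hypothesis at the end of this part was written before its value was seen, while the genes described first outside the naming rule were chosen after their values were seen.

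In the mixed cluster 8, lysosomal genes were lower in the KO library, with a median log2 ratio of -0.35 (-0.47 to -0.24), 10 of 19 over 25% lower and 0 over 25% higher. Recruitment receptors (-0.42), cholesterol efflux and LXR targets (-0.35, percentile 0.11), alternative activation genes (-0.32) and T cell effector genes (-0.66, 11 of 15 over 25% lower) were lower too. Proliferation genes (0.25, 5 of 12 over 25% higher) and cholesterol synthesis genes (0.19, percentile 99.8) were higher. In monocyte-like cluster 11, efferocytosis genes (-0.96, 6 of 8 over 25% lower) and cholesterol efflux genes (-0.50) were lower, beside the class II genes described above.

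In T cell-like cluster 1, interferon-stimulated genes were higher in the KO library (0.61, 0.24 to 0.90, 6 of 8 over 25% higher), with the ubiquitin-like modifier Isg15 at 28.5 and 74.99 CPM (1.39), while in cytotoxic cluster 4 the same list was lower. Cluster 5 held more Cd40lg, the CD40 ligand gene, in the KO library (26.6 and 55.7 CPM, 1.06, and 0.43 after thinning to 1500 UMIs per cell), and cluster 7, led by haemoglobin genes, held less Stat6 (49.2 and 25.2 CPM, -0.97). Across the macrophage-, monocyte-, cDC2-, neutrophil-, B cell- and T cell-like classes in which each could be measured, Ftl1-ps1 (median -2.06), Wdr89 (-1.20) and Snhg6 (-1.10) were lower in the KO library. Fkbp5 had a median of 1.59, from 1.25 to 2.63 outside T cell-like cells but only 0.13 within them.

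Expression differences next to Ehd1 on chromosome 19 were examined because marrow from a line made in embryonic stem cells of another strain may carry linked variants around the targeted gene. Over all kept cells, the 208 genes within 10 Mb of Ehd1 had a median absolute log2 ratio of 0.18, at percentile 99.1 of random lists matched on expression (95% of these between 0.12 and 0.17). The value met the prediction for linked variants by a small margin, at 0.175 against an upper random limit of 0.170. It does not single out linked variants. The strain history of the line is not given in the sources used here, and 1 library per genotype leaves other regions and causes open.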
